A study of Mus musculus with 6 samples.

How the data were processed

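RNA was measured in 6 libraries of DN3 thymocytes from C57BL/6 mice, 3 wild type for NMe and 3 homozygous for mutated GATA sites 1 and 2 of NMe. Per the labels' protocols, total RNA was converted to full-length cDNA and amplified with the SMART-Seq v4 kit for very small inputs, fragmented and tagged with the Nextera XT transposase, and sequenced as read pairs on an Illumina HiSeq. These kits do not record the strand of the RNA, so reads of overlapping or antisense genes cannot be assigned to one of them with certainty, and amplification can widen the spread of rare transcripts. Per the submitters' processing notes, STAR 2.5.3, featureCounts, DESeq2 1.20.0 and the mouse builds mm10 and GRCm38 were used. The annotation release, the counting options and the filter that left the listed genes are not given in the sources used here.

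The deposited values are a gene-level signal: read counts that the authors divided by 1 size factor per library, as DESeq2 does, with 1 column for each of the 6 libraries and 21135 genes. The unit was settled from the values. Within each library every value was a whole multiple of the same step, and dividing by that step gave whole reads for 100.0% of 126810 values within a tolerance of 0.1 reads. Each listed gene had at least 20 reads over the 6 libraries. Recovered reads ranged from 38.6 to 51.3 M per library, so that a gene with a mean of 10 normalised reads is measured with far less precision than one at the level of Myc. The count test of edgeR on these reads called 3283 genes and that of DESeq2 4168. The ratios of read numbers printed for genes with few reads have exact Clopper-Pearson intervals at 95%, which cover counting error only.

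Symbols, positions and biotypes came from GENCODE release M21 on GRCm38, the build that the processing notes name. A symbol was found for 21100 of the 21135 genes, and the other 35 held 0.008% of the reads. No column of any other sample was present. Counts of different libraries of a group differed far beyond sampling noise (chi-square per degree of freedom 26.7 to 55.3), so none was counted as a repeat of another. The labels number the libraries 1 to 3 in each genotype and give each its own tag, but do not say that they came from separate animals, so p-values measure the spread between these libraries.

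The test of genotype used limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a mean-variance trend) on log2(value + 1), mutant minus wild type, over 17815 genes with a mean of at least 10. It was two-sided with Benjamini-Hochberg adjustment at 0.05, and every adjusted p of a gene in the text is from this fit unless another tool is named. Fold changes are on the log2(value + 1) scale. This scale understates the change of rare transcripts whose level is even within a group. Where only some libraries of a group hold reads, the fitted change can instead exceed the ratio of mean levels. Errors of log2 changes are standard errors of the fit, and errors of levels are standard deviations over 3 libraries. A fit with the replicate number as a block was an alternative.

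Gene lists numbered 28, of which 27 had the 5 tested members needed for a test. They were tested with limma's camera at a preset correlation between genes of 0.01, with camera at an estimated correlation, and with fry, adjusted over the lists. The lists covered MYC targets, growth, metabolism, the cell cycle, Notch and T-lineage genes, stress, the neighbours of Myc, the other cells that a DN3 sort could hold, and RNA quality. A few genes sit in 2 lists, among them Slc7a5. The genes named were Myc, the 12 highest and 12 lowest log2 changes among called genes with a mean of at least 50 and no overlap between genotypes (unnamed gene models left out), up to 4 members per list with the smallest p, the neighbours of Myc, Gata3, Notch1 and the Y-linked genes. Any other gene named was chosen after its values were seen. Some genes that this rule takes are not reported here. The groups, the test, the lists, the rule for named genes and all alternatives except a correction for GC content, exon length and abundance were fixed before the data were examined.

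The alternatives were other scalings, pseudocounts, filters and variance models, library weights, the block, leaving out 1 library at a time, and count models on the recovered reads (edgeR 4.0.16, DESeq2 1.42.0 and limma's voom). Adjusted p-values that DESeq2 did not give were left out. The methods were tested on simulated counts drawn for 17815 genes with the means and depths of these libraries and 200 changed genes. The limma fit recovered 11.9% of 67 genes changed 1.5-fold, 43.3% of 67 changed 2-fold and 78.8% of 66 changed 4-fold, with 6.32% of its calls false. Far more genes were called in the libraries themselves, where the adjustment is less strict, so that these shares hold for the simulated setting only. Camera called a simulated list of 40 genes changed 1.5-fold with the preset correlation (adjusted p = 1.05e-28) and with an estimated one (adjusted p = 0.0333). Each form called 0 of 200 random lists. Simulated genes were drawn independently, so that this does not test the preset correlation itself. No spike-in was used here, so values are relative to the other genes of a library and not amounts per cell. Python 3.11.15 and pandas 2.3.3 prepared the tables.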

Results

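RNA levels were measured by RNA sequencing in DN3 thymocytes, the CD4 and CD8 double-negative stage of the mouse thymus that rearranges the T-cell receptor beta gene and depends on Notch1. NMe is the Notch-bound distal enhancer of Myc and lies in the gene-poor interval on the far side of Pvt1. In the mutant mice GATA sites 1 and 2 of NMe, motifs of the kind bound by Gata3, were mutated on both alleles. The comparison of 3 mutant with 3 wild-type libraries addresses how these sites affect Myc and the rest of the transcriptome. Recovered reads came to 47.2 ± 4.5 M per wild-type library and 43.0 ± 4.9 M per mutant library (SD, n = 3 each), with a range of 38.6 to 51.3 M. The first principal component of the log2 values held 42% of the variance and separated the genotypes. The second held 17.1% and set wild type replicate 3 (-55.1) apart from wild type replicates 1 (33.9) and 2 (23.4).

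Myc, on chromosome 15 (GRCm38, 61985391 to 61990374), was 3.54-fold lower in the mutant. Its normalised read count was 18041, 19223 and 20196 in the wild-type libraries and 5562, 4612 and 6165 in the mutant libraries (19150 ± 1080 against 5446 ± 783, SD, n = 3 each). The log2 change was -1.82 ± 0.12 (SE), with a 95% confidence interval of -2.08 to -1.56 and a limma adjusted p of 4.22e-05. Pvt1, the long noncoding RNA gene next to Myc (62037986 to 62378096), fell 3.63-fold from 299.5 ± 64.3 to 80.6 ± 6.94 (log2 change -1.86 ± 0.23, adjusted p = 0.000729). Gata3, which encodes the thymocyte factor that binds GATA motifs, rose 1.56-fold (0.64 ± 0.10, adjusted p = 0.00208). Notch1 rose 1.44-fold (0.53 ± 0.12, adjusted p = 0.0155), and missed the threshold without wild type replicate 3 (adjusted p = 0.0548) or without mutant replicate 2 (adjusted p = 0.054).

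**Figure D1:**
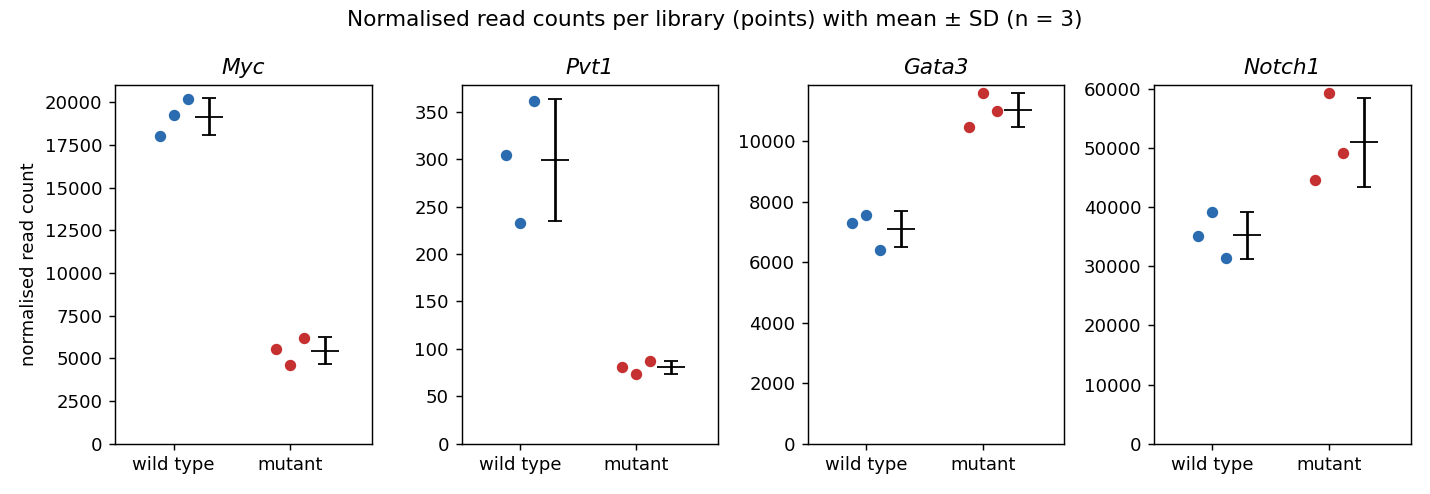
Normalised read count (linear axes from 0) of Myc, Pvt1, Gata3 and Notch1 in each wild-type (blue) and mutant (red) library, with the mean and SD of 3 libraries beside the points. The mutant libraries lie between 4612 and 6165 for Myc, below each wild-type library, and above each wild-type library for Gata3 and Notch1.

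Of 15 neighbours of Myc on chromosome 15 that were listed, 10 were tested. Pvt1 and Sqle (squalene epoxidase of sterol synthesis) fell and 0 rose, with 2 falling when adjusted over the list alone as well. Sqle changed by -0.35 ± 0.11 (adjusted p = 0.0496), and did not pass when any 1 library was left out (adjusted p 0.0556 to 0.18), nor with edgeR (adjusted p = 0.0603) or the correction for GC content, exon length and abundance (0.161). On the side of Myc away from Pvt1, the log2 changes were 0.29 ± 0.22 for Fam84b, -0.10 ± 0.47 for Trib1, -0.08 ± 0.10 for Nsmce2, -0.19 ± 0.12 for Washc5, -0.26 ± 0.12 for Ndufb9 and 0.13 ± 0.15 for Tatdn1. On the far side of Pvt1 they were -0.10 ± 0.09 for Fam49b and 0.09 ± 0.13 for Asap1. None of these 8 passed the test, with adjusted p from 0.147 (Ndufb9) to 0.903 (Trib1), and the list was not called by camera (adjusted p = 0.198), although fry called it lower (adjusted p = 0.0169).

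**Figure D2:**
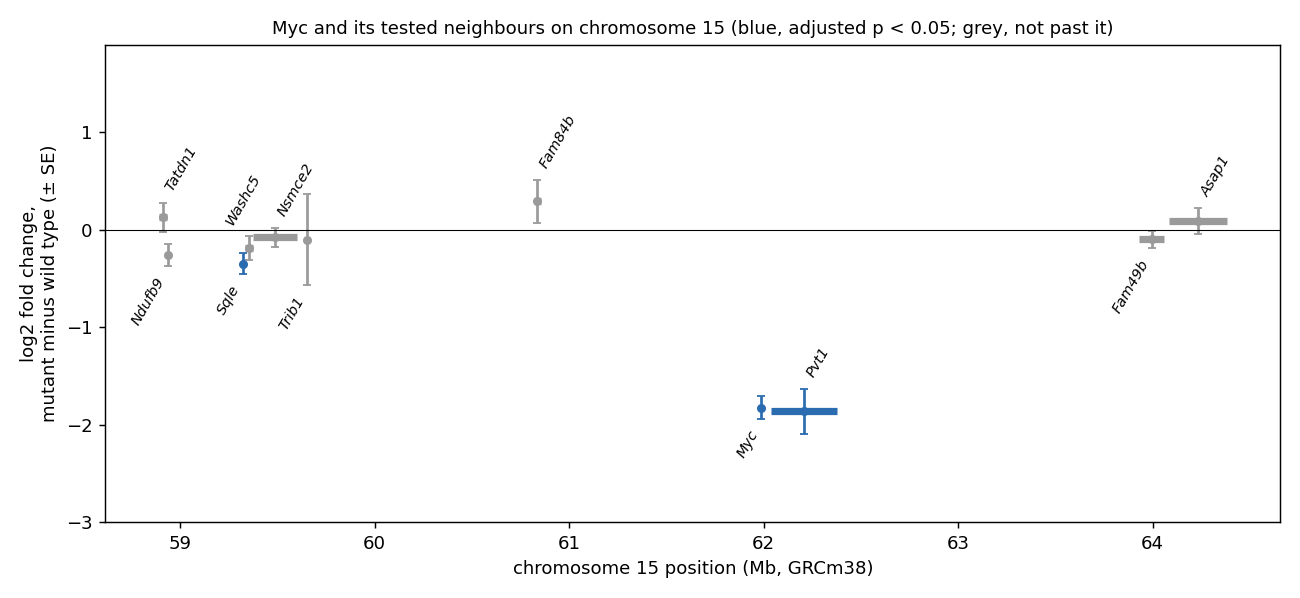
Log2 fold change (mutant minus wild type, ± SE) of Myc and its 10 tested neighbours against their position on chromosome 15 in Mb, with thick bars for the extent of each gene. Myc (-1.82) and Pvt1 (-1.86) lie far below the other genes shown.

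Across the transcriptome 3352 of 17815 tested genes changed (18.8%), with 1414 higher and 1938 lower in the mutant. Among them 509 rose and 445 fell at least 2-fold. The median log2 change of all tested genes was 0.03. The 3 libraries of each genotype did not overlap for 6821 genes (38.3%, where chance gives 10%). With every library rescaled to the same total the split turned to 1827 higher and 1647 lower. Without wild type replicate 2 the count dropped to 1905 (819 higher and 1086 lower), and without mutant replicate 2 the genes higher in the mutant numbered 852.

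The named genes with the largest rise were led by Rhobtb3, at 7.30 ± 5.84 normalised reads in the wild type and 904 ± 194 in the mutant (log2 change 7.15 ± 0.61, adjusted p = 0.000142, and 6.30 without wild type replicate 2). B4galnt2, a glycosyltransferase gene, rose from 35.3 ± 5.02 to 950.4 ± 253 (4.69 ± 0.24, adjusted p = 2.25e-05), and the interferon-inducible Ifi204 from 40.1 ± 7.19 to 804.9 ± 227 (4.27 ± 0.27, adjusted p = 4.13e-05). Fam20a rose by 3.93 ± 0.36, the protocadherin gene Pcdh7 by 3.49 ± 0.41, the teneurin gene Tenm4 by 4.21 ± 0.67 (4.86 without mutant replicate 2) and Olfm5 by 3.46 ± 0.38 on the log2 scale. Arnt2, which encodes a partner of basic helix-loop-helix factors, rose by 5.80 ± 0.78 on the log2 scale (6.76 without wild type replicate 1), with 6 reads over the wild-type libraries, each in replicate 1, and 332 over the mutant libraries, a 58.2-fold ratio after scaling (95% counting interval 26.5 to 160). 

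In 4 of these genes the level within a genotype varied widely or reads can be shared with related genes. Ifi211, a neighbour and relative of Ifi204 on chromosome 1, rose by 4.35 ± 1.18 with mutant levels of 162, 63.4 and 4139. Its change was 2.57 without mutant replicate 3 (adjusted p = 0.0107) and 5.57 without mutant replicate 2, and it missed the threshold when any 1 wild-type library was left out (adjusted p up to 0.0741) and with voom (adjusted p = 0.24). The remaining 3 lie on chromosome 17. Smok4a, a transcribed pseudogene (13521456 to 13528433), rose by 3.62 ± 0.37. Btnl2 (34354822 to 34369495) rose by 5.76 ± 1.07, with wild-type reads in replicate 3 (27 reads) and 0 in the other wild-type libraries, and DESeq2 did not call it (adjusted p = 0.127). Its change was 7.31 without that replicate and 4.99 without wild type replicate 1 or 2. The class I histocompatibility gene H2-Q1 (35320405 to 35325099) had 2692 normalised reads in wild type replicate 3, near the mutant mean of 3137, against 76.3 and 44.9 in wild type replicates 1 and 2. Its change of 3.88 ± 1.17 (adjusted p = 0.0439) was lost with edgeR (adjusted p = 0.302) and on leaving out any library other than wild type replicate 3 (adjusted p up to 0.14), while without that replicate it was 5.71 (adjusted p = 3.82e-06).

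The lowest was Syn2, a synapsin gene, with 469 reads over the wild-type and 4 over the mutant libraries (log2 change -6.18 ± 0.60, a 111-fold ratio of reads, 95% counting interval 43.2 to 411). Bcat1, the cytosolic branched-chain aminotransferase, fell from 1435 ± 418 to 84.3 ± 20.2 (-4.06 ± 0.25, adjusted p = 4.13e-05). Asns, asparagine synthetase, fell from 262.3 ± 85.9 to 32.6 ± 11.7 (-2.98 ± 0.33, adjusted p = 0.000434). Genes of protein folding in the endoplasmic reticulum were among them, Pdia5 (-3.83 ± 0.30) and Fkbp11 (-3.01 ± 0.33), as were the adenylate kinase gene Ak4 (-2.92 ± 0.31) and the transcription factor gene Gfi1b (-2.96 ± 0.37). Fam171a1 (-3.70 ± 0.40), Tmem238 (-3.60 ± 0.41), Prr5 (-2.97 ± 0.20) and Pcsk4 (-2.90 ± 0.18) fell too. Alpl, alkaline phosphatase, fell by 3.69 ± 0.91 on the log2 scale from a wild-type level of 680 ± 664 (-4.82 without mutant replicate 2, -2.85 without mutant replicate 3 and -2.93 without wild type replicate 3), and lost its call on leaving out wild type replicate 3 (adjusted p = 0.0602) or mutant replicates 1 (0.0685) or 3 (0.0529), and with robust empirical Bayes (0.141).

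**Figure D3:**
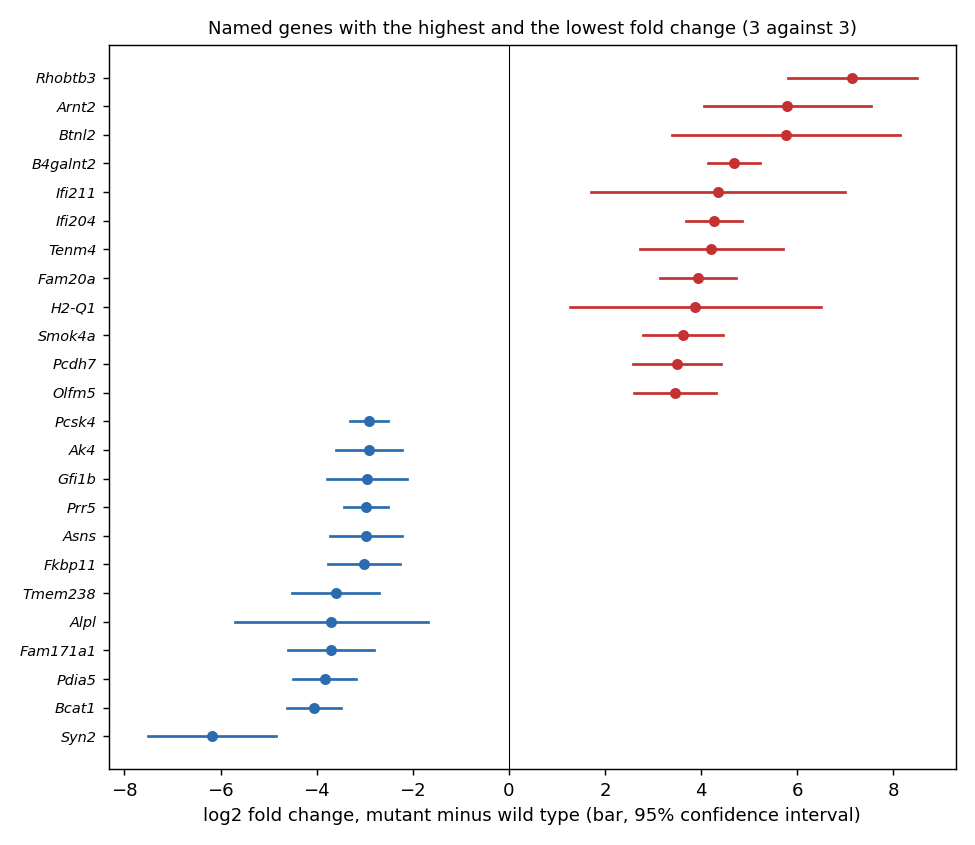
Log2 fold change (mutant minus wild type) of the 12 named genes with the highest and the 12 with the lowest change, with 95% confidence intervals from 3 against 3 libraries. Rhobtb3 (7.15) and Syn2 (-6.18) mark the ends, and the intervals of Btnl2, Ifi211, H2-Q1 and Alpl are among the widest.

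MYC target genes were lower in the mutant. Of 55 tested members 46 fell and 0 rose (50 fell adjusted over the list alone), with a median log2 change of -0.82. The camera test called the list lower at adjusted p = 1.94e-29, and not at adjusted p = 0.231 with an estimated correlation. The folate carrier gene Slc19a1 fell 3.09-fold (3977 ± 162 to 1287 ± 61), Polr1b of RNA polymerase I fell 3.05-fold (6267 ± 415 to 2057 ± 235), the spermidine synthase gene Srm fell 2.72-fold (13800 ± 1320 to 5063 ± 213) and the nucleolar Npm1 fell 2.64-fold (49900 ± 4220 to 18890 ± 820). Their adjusted p ranged from 4.22e-05 to 6.46e-05. 

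Genes of ribosome biogenesis fell as a group, 43 of 46 members (44 adjusted over the list alone) with a median of -0.72 and 0 risen (camera adjusted p = 4.72e-28, and adjusted p = 0.231 with an estimated correlation). Dkc1, which encodes the pseudouridine synthase dyskerin, changed by -1.18 ± 0.10, and the assembly factor genes Noc2l, Rrp1b and Wdr12 by -1.08 ± 0.09, -1.06 ± 0.09 and -1.08 ± 0.10. Among 46 genes of cytosolic ribosomal proteins 44 fell and 0 rose (44 fell adjusted over the list alone). The 2 that did not pass, Rpl24 (-0.32) and Rps14 (-0.11), were named after their values were seen. The median of this list was -0.82 (camera adjusted p = 6.25e-30, and adjusted p = 0.29 with an estimated correlation). Rpl3 fell from 48840 ± 666 to 22410 ± 606 (-1.12 ± 0.08, adjusted p = 5.89e-05), and Rplp0, Rpl4 and Rpl14 changed by -0.98 ± 0.10, -0.99 ± 0.10 and -0.97 ± 0.10. Genes with symbols of Rpl or Rps and a digit took 3.44%, 3.44% and 3.26% of the reads of the wild-type libraries and 2.40%, 2.02% and 1.86% of those of the mutant libraries. This set differs from the list, since it leaves out Rplp0 and takes in some genes of other kinds.

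Metabolic genes fell with them. Of 27 genes of nucleotide synthesis and one-carbon metabolism 22 fell and 0 rose (23 fell adjusted over the list alone), with a median of -0.75 (camera adjusted p = 5.01e-18, and adjusted p = 0.248 with an estimated correlation). The serine hydroxymethyltransferase genes Shmt1 and Shmt2 fell 2.55-fold and 2.53-fold, Mthfd1 of the folate cycle 2.42-fold and Gart of purine synthesis 2.10-fold. In the list of glycolysis and nutrient transport 18 of 24 genes fell and 1 rose (18 and 2 adjusted over the list alone), with a median of -0.68 (camera adjusted p = 2.26e-10, and adjusted p = 0.231 with an estimated correlation). The glycolytic genes Tpi1, Pfkp, Ldha and Pkm fell 2.81-fold, 2.25-fold, 2.20-fold and 2.05-fold. The gene that rose, named after its value was seen, was the hexokinase gene Hk1 (0.37 ± 0.10, adjusted p = 0.0314). Of 30 genes of the mitochondrial respiratory chain 19 fell and 0 rose (22 fell adjusted over the list alone), by less (median -0.36, camera adjusted p = 6.86e-10, and adjusted p = 0.306 with an estimated correlation). The ATP synthase genes Atp5a1 and Atp5b changed by -0.61 ± 0.09 each, Cycs (cytochrome c) by -0.56 ± 0.10 and Sdhd of succinate dehydrogenase by -0.55 ± 0.11.

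Genes of DNA replication fell in 25 of 40 cases, with 0 risen (27 fell adjusted over the list alone) and a median of -0.46 (camera adjusted p = 6.95e-13, and adjusted p = 0.294 with an estimated correlation). The helicase gene Mcm6 fell from 52560 ± 4050 to 34050 ± 3380 (-0.63 ± 0.10), Mcm10 by 0.79 ± 0.13, Pold2 of DNA polymerase delta by 0.62 ± 0.09 and the clamp loader gene Rfc5 by 0.59 ± 0.10 on the log2 scale. Of 32 mitosis genes Cdk1 (-0.46 ± 0.12, adjusted p = 0.0274) and Cdc20 (-0.37 ± 0.11, adjusted p = 0.0457) fell and 0 rose, with 0 called adjusted over the list alone. The call of Cdk1 was lost on leaving out wild type replicates 2 or 3 or mutant replicates 1 or 2 (adjusted p up to 0.0893), and that of Cdc20 on leaving out any library other than mutant replicate 3 (up to 0.141). Neither passed with equal library totals (adjusted p = 0.0517 for Cdk1 and 0.09 for Cdc20) or with the correction for GC content, exon length and abundance (0.0864 and 0.203). Bub1b (-0.50 ± 0.16) and Plk1 (-0.45 ± 0.15) of the mitotic spindle did not pass. Both were called without mutant replicate 3 (adjusted p = 0.00806 and 0.0178), with DESeq2 (0.0267 and 0.0302) and with library weights (0.0272 and 0.0308), Bub1b also over genes with a mean of at least 50 (0.0498) and Plk1 with robust empirical Bayes (0.0443). The median of the mitosis list was -0.08 and camera did not call it (adjusted p = 0.11), although it did without wild type replicate 1 (0.00737) or mutant replicate 3 (0.000141).

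Inhibitors of the cell cycle and quiescence genes rose in 9 of 16 cases with 0 fallen (11 rose adjusted over the list alone), with a median of 0.65 (camera adjusted p = 3.11e-06, and adjusted p = 0.29 with an estimated correlation). The inhibitor genes Cdkn2d and Cdkn1a rose 2.22-fold and 1.73-fold, and Btg1 and Ccng2, both antiproliferative, rose 2.27-fold and 1.51-fold. In the network of MYC partners and antagonists 2 of 12 genes rose and 0 fell (2 and 0 adjusted over the list alone), and camera did not call the list (median 0.04, adjusted p = 0.515). Mycn, the MYC paralogue, rose 3.12-fold from 1445 ± 472 to 4432 ± 991 (1.64 ± 0.23, adjusted p = 0.00126). The antagonist gene Mxd3 rose by 0.42 ± 0.12 (adjusted p = 0.0397), a call lost on leaving out any library other than wild type replicate 3 (adjusted p up to 0.125) and with the correction for GC content, exon length and abundance (0.0635). Mxd1 (0.57 ± 0.20) and Mga (-0.33 ± 0.13) did not pass. With that correction both were called (adjusted p = 0.0396 and 0.0164), and Mxd1 also without mutant replicate 1 (0.0307), with DESeq2 (0.00952) and with library weights (0.0493).

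Notch target genes were higher in the mutant, 5 of 12 having risen and 0 fallen (9 rose adjusted over the list alone), with a median of 0.76 (camera adjusted p = 3.73e-06, and adjusted p = 0.248 with an estimated correlation). Dtx1 rose 3.75-fold (5618 ± 81 to 21120 ± 1700, adjusted p = 2.25e-05), and Il2ra, which encodes the CD25 marker of DN3 cells, rose 1.80-fold (58950 ± 2810 to 106100 ± 8060, adjusted p = 0.000364). Hes1 rose by 0.86 ± 0.23 (adjusted p = 0.0252), a call lost on leaving out wild type replicates 2 or 3 or mutant replicates 1 or 3 (adjusted p up to 0.0948) and with robust empirical Bayes (0.0844). Besides Notch1, the fifth was Heyl (0.78, adjusted p = 0.0428), named after its value was seen. Of 20 transcription factors of the T lineage 5 rose and 1 fell (8 and 1 adjusted over the list alone). Lef1 rose 2.23-fold, Tox 1.72-fold, Gata3 1.56-fold and Id2 2.37-fold. Myb (0.49) rose and Spib (-1.15) fell, both named after their values were seen. This list had a median of 0.23 (camera adjusted p = 0.0442, and adjusted p = 0.29 with an estimated correlation) and was not called without wild type replicate 2 (0.0528) or mutant replicate 2 (0.0637).

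Genes of V(D)J recombination and pre-T-cell receptor signalling rose in 9 of 20 cases (10 adjusted over the list alone), and 1 fell in both counts. The median was 0.33 (camera adjusted p = 0.000107, and adjusted p = 0.294 with an estimated correlation). The kinase gene Prkcq rose 1.7-fold, the adhesion gene Cd2 3.16-fold (208.5 ± 43.5 to 684.9 ± 248) and Cd3d of the receptor complex 1.6-fold, while the recombinase gene Rag1 fell 1.5-fold (10200 ± 314 to 6835 ± 694, adjusted p = 0.0035). Of 17 genes of the response to beta-selection, the checkpoint that follows a productive beta chain, 8 rose and 1 fell (9 and 1 adjusted over the list alone). Cd5 rose 2.04-fold, the survival gene Bcl2l1 1.53-fold and Cd27 1.39-fold, and the amino acid transporter gene Slc7a5 fell 2.57-fold. The list had a median of 0.61 (camera adjusted p = 0.00184, and adjusted p = 0.306 with an estimated correlation). Genes of the immediate early and heat shock response, a sign of how cells were handled, had a median of 0.58 in the same libraries. Of 13 of them Ier2 rose (0.80 ± 0.24, adjusted p = 0.0455) and 0 fell, with 0 called adjusted over the list alone. Dnajb1 (0.68 ± 0.22), Jun (0.66 ± 0.25) and Hspa8 (-0.42 ± 0.15) did not pass. Dnajb1 was called without wild type replicate 1 (adjusted p = 0.0393) or mutant replicate 2 (0.00655), and with equal library totals (0.0485), edgeR (0.0476), DESeq2 (0.00462) and the correction for GC content, exon length and abundance (0.026). Jun was called without wild type replicate 1 (0.0176), and Hspa8 without mutant replicate 1 (0.0427) and with library weights (0.0273). Camera called this list higher (adjusted p = 0.0494, and adjusted p = 0.637 with an estimated correlation), and fry did not (adjusted p = 0.41). On leaving out wild type replicates 2 or 3 or mutant replicates 1 or 3 the calls of the list (adjusted p up to 0.326) and of Ier2 (up to 0.136) were lost, and edgeR did not call Ier2 (0.0547).

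Genes of gamma-delta T cells, the lineage that branches off before beta-selection, rose in 10 of 11 cases with 0 fallen (10 adjusted over the list alone), with a median of 0.80 (camera adjusted p = 1.83e-06, and adjusted p = 0.231 with an estimated correlation). The delta constant gene Trdc rose from 9615 ± 1410 to 16790 ± 2720 (1.74-fold), Cd163l1 2.11-fold, Etv5 1.93-fold and Blk 1.68-fold. Of 16 genes of the interferon response 8 rose and 1 fell (10 and 1 adjusted over the list alone), with a median of 0.77 (camera adjusted p = 9.56e-05, and adjusted p = 0.377 with an estimated correlation). Usp18 rose 2.60-fold, Isg15 1.99-fold and Irf7 1.97-fold, and Bst2, named after its value was seen, fell (-0.58, adjusted p = 0.0468). The list was not called by fry (adjusted p = 0.0884).

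Genes of DNA damage and apoptosis moved both ways, 3 of 19 up and 3 down (3 and 3 adjusted over the list alone, median 0.02, camera adjusted p = 0.708). The survival gene Bcl2 rose from 9027 ± 1320 to 18430 ± 2330 (1.03 ± 0.13, adjusted p = 0.000847). Mcl1 (0.41) and Zmat3 (0.80), named after their values were seen, rose too, and the proapoptotic Bid (-0.61 ± 0.13) and Bcl2l11 (-0.48 ± 0.12) and the nuclease gene Aen (-0.51 ± 0.11) fell. The call of Bcl2l11 was lost on leaving out any library other than mutant replicate 3 (adjusted p up to 0.0657), and that of Aen without wild type replicate 2 (0.0663). In the integrated stress response 3 of 11 genes fell and 1 rose (3 and 2 adjusted over the list alone, median -0.12, camera adjusted p = 0.262, fry adjusted p = 0.0419). Beside Asns the serine synthesis genes Phgdh (-0.74 ± 0.09) and Psat1 (-0.97 ± 0.14) fell, while the stress factor gene Ddit3 rose (0.57 ± 0.15), a call lost on leaving out wild type replicate 3 or any 1 mutant library (adjusted p up to 0.0619).

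**Figure D4:**
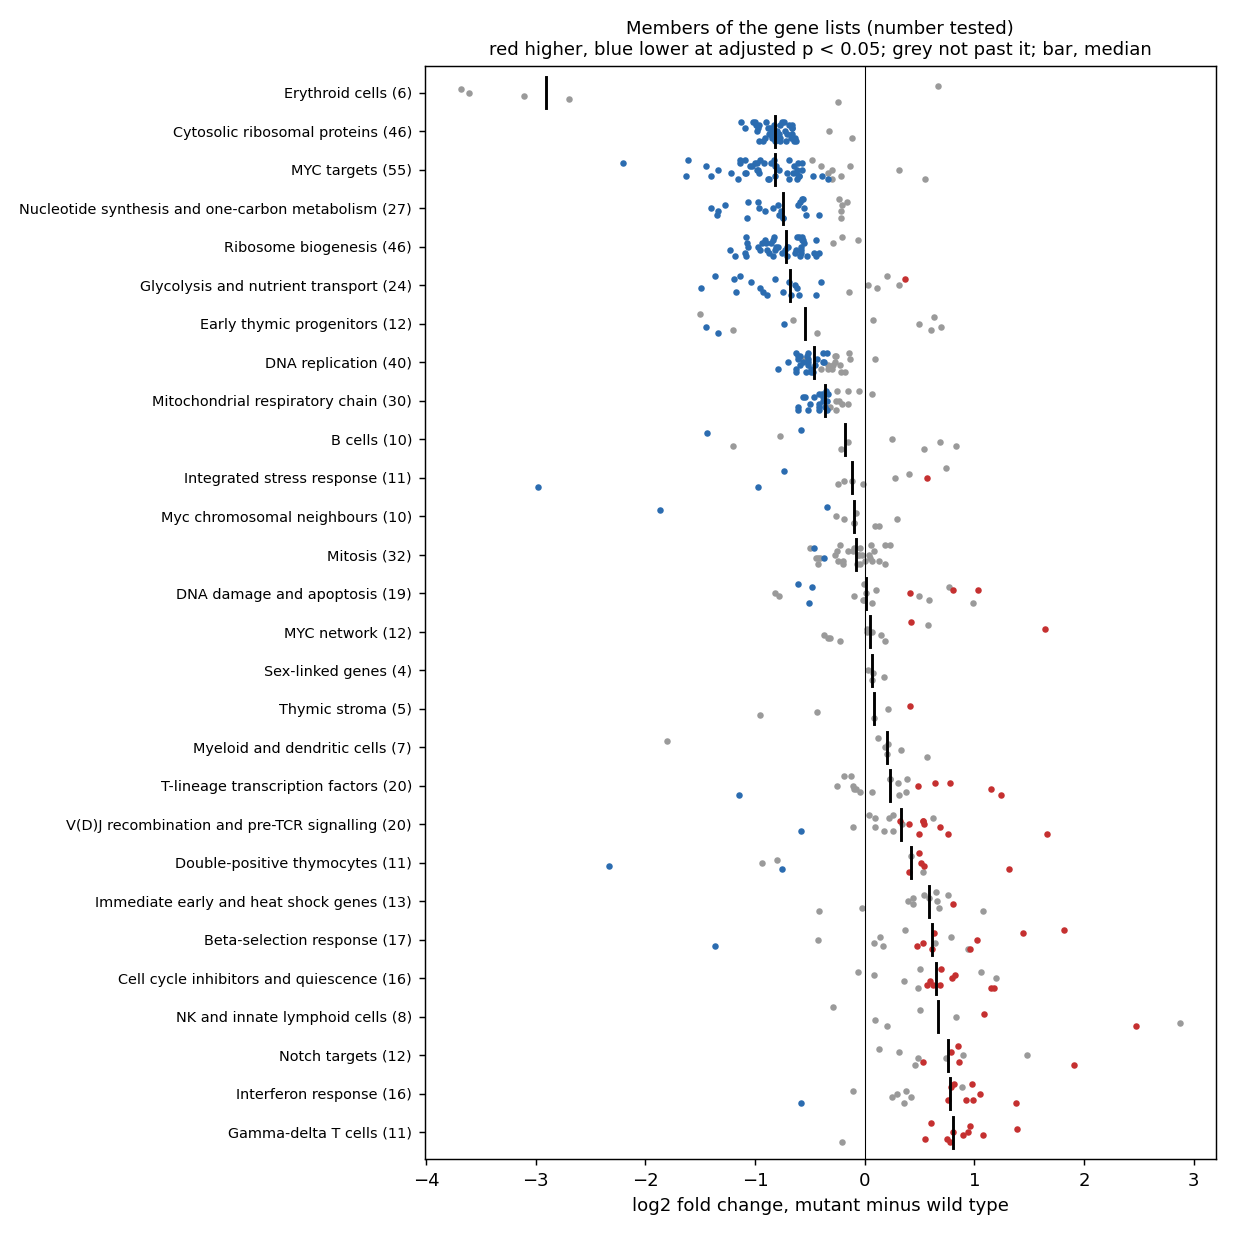
Log2 fold change (mutant minus wild type) of each tested member of the 28 gene lists, one row per list with its number of tested members, with a black bar at the median. Points are red or blue where the adjusted p over all genes is under 0.05, and the lists of ribosomal proteins, MYC targets and ribosome biogenesis (medians -0.82, -0.82 and -0.72) lie almost wholly below 0.

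Markers of further cell types that the DN3 sort could hold were not called as lists by camera at the preset correlation. Of 12 genes of early thymic progenitors 3 fell and 0 rose (6 and 0 adjusted over the list alone, median -0.55, camera adjusted p = 0.117), namely Bcl11a (-1.34 ± 0.24), Cd44 (-1.45 ± 0.28) and Mef2c (-0.74 ± 0.20), the last not without wild type replicates 1 or 3 or mutant replicate 1 (adjusted p up to 0.0899). Kit (-0.43 ± 0.15) did not pass, but was called without mutant replicate 2 (adjusted p = 0.0472) and with DESeq2 (0.0398). Of 11 genes of double-positive thymocytes 5 rose and 2 fell (5 and 3 adjusted over the list alone), with a median of 0.42 and a mean of -0.05 of opposite sign (camera adjusted p = 0.208, direction up). Over genes with a mean of at least 50 camera called both of these lists (adjusted p = 0.0251 and 0.0415). Slamf1 rose 2.48-fold, Themis 1.43-fold and Arpp21 1.33-fold (for Arpp21 not without wild type replicate 1, adjusted p = 0.0542, or mutant replicate 2, adjusted p = 0.0572), and Tdrd5 fell 5.04-fold. Of 10 B-cell genes 0 rose and 2 fell (1 and 2 adjusted over the list alone, median -0.18, camera adjusted p = 0.44), the class II gene H2-Ab1 (836 ± 86.1 to 308.1 ± 35.9) and Ighm (-0.58 ± 0.10). H2-Ab1 lies on chromosome 17 (34257689 to 34269419), in the same stretch as Btnl2 and H2-Q1. Vpreb1 (0.83 ± 0.27) and Cd74 (-1.20 ± 0.67) did not pass. Cd74 was called without wild type replicate 3 (adjusted p = 0.0212), and Vpreb1 with equal library totals (0.044), edgeR (0.0498), DESeq2 (0.0127) and the correction for GC content, exon length and abundance (0.0474).

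Of 8 genes of NK and innate lymphoid cells Nkg7 (2.12-fold) and Xcl1 rose and 0 fell (2 and 0 adjusted over the list alone, median 0.67, camera adjusted p = 0.0738), Nkg7 not with robust empirical Bayes (adjusted p = 0.0642). Xcl1 went from 6.94 ± 4.16 to 41.1 ± 14.6 (adjusted p = 0.0118, and 0.0501 without mutant replicate 3), and Gzma (0.20 ± 0.13) and Gzmb (2.87 ± 1.17) did not pass, but Gzmb was called without wild type replicate 1 (adjusted p = 0.0114) and Gzma with the correction for GC content, exon length and abundance (0.0405). This list was called on leaving out wild type replicate 1 (adjusted p = 0.0195) or mutant replicate 3 (0.0424). Among 7 myeloid and dendritic genes 0 changed in both adjustments, with a median of 0.21 and a mean of -0.03 of opposite sign (camera adjusted p = 0.493). Cst3 was at 3804 ± 241 and 4442 ± 890, Lyz2 at 1337 ± 238 and 1584 ± 465, Cd68 at 125 ± 38.6 and 181 ± 32.4 and Mpo at 25.5 ± 37.7 and 3.41 ± 3.31 in the wild type and the mutant. In thymic stroma 1 of 5 genes rose and 0 fell (1 and 0 adjusted over the list alone), Pecam1 (0.41 ± 0.11, lost on leaving out any library other than mutant replicate 3, adjusted p up to 0.108), with a median of 0.09 and a mean of -0.14 of opposite sign (camera adjusted p = 0.708). Epcam (0.21 ± 0.17), Col1a1 (-0.44 ± 0.56) and Cldn4 (-0.95 ± 0.39) did not pass, Cldn4 except without mutant replicate 2 (adjusted p = 0.0231).

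Of 6 erythroid genes 0 changed in both adjustments (median -2.90, camera adjusted p = 0.434). Haemoglobin transcripts took 0.0174% of the reads of wild type replicate 2 and at most 0.0001% of those of any other library. Hbb-bs, Hbb-bt and Hba-a2 had wild-type means of 1182, 247.2 and 315.5 with SDs of 2030, 413 and 545, and Hbb-bt was called without wild type replicate 3 (adjusted p = 0.0264) and by edgeR (0.0408), as was Hbb-bs by edgeR (0.0453). Klf1 changed by 0.67 ± 0.40 and did not pass. Of the 6 sex-linked genes listed 4 were tested, each Y-linked, and 0 changed in both adjustments (median 0.07). Ddx3y was at 5956 ± 600 and 6256 ± 790, Eif2s3y at 3614 ± 1240 and 3932 ± 492, Kdm5d at 2060 ± 220 and 2193 ± 504 and Uty at 3412 ± 417 and 3474 ± 424 in the wild type and the mutant.

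Camera with the preset correlation called 15 of the 27 lists, 8 higher and 7 lower in the mutant, and 0 with an estimated correlation. Fry called 15 as well, of which 13 were shared with camera in the same direction. It did not call the interferon response or the immediate early and heat shock genes. In their place it called the integrated stress response and the neighbours of Myc. Another split of the 6 libraries into 3 and 3, across genotypes, gave 17 lists by camera. That split mixed the genotypes unevenly and was not free of the genotype difference. The counts of single genes in each list do not depend on that correlation.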

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

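The correction for GC content, exon length and abundance was chosen after the data were seen, and the other alternatives before. The log2 change of Myc lay between -1.92 and -1.69 over 19 alternatives, each past the threshold (adjusted p 4.37e-38 to 0.000618). The count of changed genes was 3066 to 4168 with all 6 libraries, the most with DESeq2. In simulated data with 200 changed genes 21.9% of its calls were false, a share that does not carry over to these libraries, where far more genes were called. Leaving out 1 library gave 1905 to 2788 genes, 819 to 1176 of them higher and 1086 to 1780 lower, and -1.92 to -1.71 for Myc. The lowest total came without wild type replicate 2, and fewer libraries alone lower such a count. Over 142 named results and 2687 comparisons, 2547 kept their direction and their side of the threshold, 89 fell below it, 39 passed it and 12 reversed, with 0 of the reversed having been called. The reversed were Kdm5d (-0.02 with the correction, -0.014 without wild type replicate 2 and -0.10 without mutant replicate 2), Uty (-0.105 with the correction, -0.049 without wild type replicate 2 and -0.058 without mutant replicate 3), Trib1 (0.335, 0.096 and 0.22 without wild type replicate 1 and mutant replicates 1 and 2), Ddx3y (-0.007) and Asap1 (-0.004) without wild type replicate 2 and Eif2s3y (-0.124) without wild type replicate 3. The cause was not tested. Over the libraries left out in turn, the highest changes were 0.404 for Eif2s3y, 0.177 for Ddx3y, 0.228 for Kdm5d, 0.121 for Uty and 0.179 for Asap1, and the lowest for Trib1 was -0.619. Erythroid cells turned upward in the camera test without wild type replicate 2 (adjusted p = 0.732, against 0.0616 without wild type replicate 3), the library that held the haemoglobin reads. Of gene lists, camera called 15, and 0 with an estimated correlation (estimates up to 0.829, but 0.013 for the T-lineage transcription factors, against the preset 0.01). In the simulated list, whose genes were drawn independently, camera gave an adjusted p of 1.05e-28 with the preset and 0.0333 with the estimated correlation. The estimated form thus raised the p-value without correlated genes, but that list stayed called, adjusted together with the 200 random lists. For MYC targets the estimate was 0.159 and the unadjusted camera p with it was 0.00993. For ribosome biogenesis the estimate was 0.383. How far correlated genes account for the loss of calls was not tested. Leaving out 1 library gave 13 to 17 lists. The sign of each of the 28 list medians was the same under the deposited, TMM, equal-total and upper-quartile scalings. With the replicate number as a block, 3066 genes and 17 lists were called, the lists of mitosis (adjusted p = 0.0299) and of NK and innate lymphoid cells (0.0417) among them, as were Bub1b (0.0121), Plk1 (0.02), Vpreb1 (0.0486) and Dnajb1 (0.0175), and deviations of same-numbered libraries did not correlate (-0.02, -0.07 and -0.01). DESeq2 gave no adjusted p for Ifi211, H2-Q1, Hbb-bt, Hbb-bs, Hba-a2 and Col1a1, and the higher filter left Mpo, Xcl1, Gzmb, Klf1 and Col1a1 untested. In simulated data at this depth, with 3 libraries per group and 200 changed genes, 11.9% of 1.5-fold changes were recovered. With 18.8% of tested genes called here the adjustment is less strict, so that this share does not carry over to the libraries themselves.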

Other observations

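Families of genes that share a symbol stem were compared after the data were seen, and each gene named in this and the next paragraph was chosen after its values were seen. Of 215 families with at least 8 tested members camera called 46, 15 higher and 31 lower in the mutant, and 0 with an estimated correlation. T-cell receptor beta variable genes rose, 21 of 26 with 0 fallen and a median log2 change of 0.81 (camera adjusted p = 2.42e-11, and adjusted p = 0.694 with an estimated correlation), among them Trbv17 (0.99 ± 0.16), Trbv31 (0.95 ± 0.16) and Trbv15 (0.88 ± 0.14). Transcripts of rearranged and of unrearranged variable genes were not told apart. Of 9 genes of the Gimap family, GTPases of lymphocytes and the noncoding Gimap1os, 7 rose and 0 fell (adjusted p = 0.000168, and adjusted p = 0.694 with an estimated correlation), among them Gimap8 (2.72 ± 0.21), Gimap1os (1.34 ± 0.24) and Gimap7 (1.25 ± 0.22). Guanylate-binding protein genes rose in 6 of 11 cases with 0 fallen (adjusted p = 6.82e-05, and adjusted p = 0.694 with an estimated correlation), such as Gbp8 (2.02 ± 0.36) and Gbp11 (0.89 ± 0.14). Reads of close relatives within these 3 families can be shared.

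Downward, 32 of 53 genes of the Eif family, translation initiation factors and their regulators, fell and 0 rose (adjusted p = 6.08e-13, and adjusted p = 0.694 with an estimated correlation), with Eif4ebp1, an inhibitor of the cap-binding factor, at -2.05 ± 0.18 and Eif3b at -0.86 ± 0.09. The CCT chaperonin that folds actin and tubulin fell in 7 of 8 genes with 0 risen (adjusted p = 4.89e-05, and adjusted p = 0.694 with an estimated correlation), from Cct6a (-0.94 ± 0.10) to Cct8 (-0.53 ± 0.11). Genes of mitochondrial ribosomal proteins of the large subunit fell in 25 of 48 cases with 0 risen (median -0.36, adjusted p = 2.33e-11, and adjusted p = 0.716 with an estimated correlation). In the interval between Pvt1 and Fam49b, which holds NMe, the long noncoding RNA gene Gm49014 on chromosome 15 (63255904 to 63278780, starting 1.27 Mb beyond the start of Myc) fell from 371 to 122 reads (-1.46 ± 0.33, adjusted p = 0.0138). Gm41335, whose model spans it (63176838 to 63718289), had 80 reads over the wild-type and 1 over the mutant libraries (76-fold, 95% counting interval 13.3 to 3040), and the pseudogene Tsg101-ps in the same interval changed by -0.09 ± 0.20. Gm41335 and Gm49014 overlap, so that reads could not be assigned to one of them with certainty. Of 46 tested genes within 5 Mb of Myc 7 were called (15.2%, against 18.8% of all tested genes, Fisher's exact p = 0.705).

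The tests below were chosen after the results were seen, except the counts over other splits of the libraries. MYC target genes fell by a median of 0.82 on the log2 scale. The values below argue against 3 technical or compositional causes of the whole, the last only if levels per dividing cell stayed the same. A scaling error moves every gene alike, whereas the list's median lay -0.844 from that of all other tested genes. After the correction for GC content, exon length and abundance the median was -0.723 and 46 members were called. A smaller share of dividing cells needs mitosis genes to fall as much, if their level per dividing cell stayed the same. Their median was -0.083 (quartiles -0.261 and 0.039), although genes of DNA replication fell. The quartiles are a spread over genes that varied together (estimated correlation 0.824) and not an error over libraries. Levels per dividing cell were not measured. Camera did call the mitosis list lower without wild type replicate 1 (adjusted p = 0.00737) or mutant replicate 3 (adjusted p = 0.000141), so that a small fall in dividing cells is not excluded. A lower output of the MYC programme stays open as a hypothesis that no test here decided, and total RNA per cell was not measured.

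Called genes with at least 4-fold changes clustered on chromosome 17, with 6 of 188 at 12 to 14 Mb and 5 at 34 to 36 Mb. In 10000 shuffles of the calls over the tested genes, 6 were reached in any 2-Mb window at a rate of 0.0057, and 5 at 0.0469. The shuffles treat genes as independent, whereas Tcte2 and Afdn, both among the 6, overlap and can share reads. At 34 to 36 Mb, the histocompatibility region, 8 of 9 genes with at least 4-fold higher fitted levels in the mutant, such as BC051537 (24.4, 42.0 and 670 in the wild-type libraries and 715 to 1123 in the mutant libraries) and H2-Q1, lay nearer to the mutant mean in wild type replicate 3, against 16.1% of such genes elsewhere. Lower Myc in that library is argued against by its Myc level, 0.117 (log2) above the mean of the other wild-type libraries. A chromosome segment that differs between animals may account for it, but this was not decided. Of the 323 genes that set this library over 2 (log2) apart from the other wild-type libraries, 12 lay in that window, more than in any other. That number was reached at a rate of 1e-04, the smallest that 10000 shuffles can give. The rate was 0.025 for the same window in wild type replicate 1, whose comparison includes replicate 3. It was 0.0205 for a window of chromosome 4 in mutant replicate 2. The count of 12 largely restates the pattern, and cannot tell a segment from neighbouring genes that vary together for another reason. At 12 to 14 Mb the 6 genes, among them Tcte2 (284 to 488 in the wild type and 2655 to 4056 in the mutant), Afdn and Smok4a, some of them overlapping, were nearer to the mutant mean in 0 wild-type libraries, so that a segment held by each mutant animal and an effect of the enhancer mutation cannot be told apart.

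Camera with the preset correlation called beta-selection genes higher (adjusted p = 0.00184), and immediate early and heat shock genes narrowly so (adjusted p = 0.0494). Neither list was called with an estimated correlation (adjusted p = 0.306 and 0.637). Of the immediate early and heat shock genes 1 of 13 was called, and fry did not call the list (adjusted p = 0.41). Its camera call was lost in 4 of the fits that left out 1 library (adjusted p up to 0.326). The 11 beta-selection genes outside the immediate early genes had a median of 0.48, with 5 risen and 1 fallen, and the list of immediate early and heat shock genes had a median of 0.582. For both, handling of the cells and genotype cannot be told apart, because the order of preparation is not in the labels. A larger share of cells past beta-selection would lower Notch targets if their level per cell stayed the same. Their median was 0.761 with a lower quartile of 0.476. Notch1 itself rose 1.44-fold, and a rise per cell could hide such a shift, so that these values do not decide it. The shares of cells by stage were not measured here.

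Over the 10 splits of the 6 libraries into 3 and 3, the real split called 3352 genes, the only 1 with as many, and the highest other split called 2. The real split called 15 gene lists by camera, 4 of the 10 splits called as many, and the highest other split called 17. With 10 splits no share under 0.05 can be shown. Each of the other splits mixed the genotypes unevenly, so that part of the genotype difference remained in it.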
